A study of Drosophila melanogaster with 3 samples.

How the data were processed

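The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of the Drosophila melanogaster protein encoded by CG13296, tagged with green fluorescent protein (GFP) and precipitated through the tag. Chromatin came from whole embryos of both sexes aged 6 to 18 hours and was sonicated to fragments of 200 to 800 bp, per the labels. There was 1 group with 3 biological replicates, which the labels record as separate biosamples. The labels conflict in 2 places. The sample description calls the libraries an input control, whereas the assay title, the antibody tag and the derivation records deposited with the peak lists name these alignments as the immunoprecipitated side, set against 1 shared control file. An age tag also holds an impossible number of hours, and the age in the source name was used instead.

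The authors deposited a relaxed peak list for each replicate, a relaxed list for the pooled replicates, each with 30000 peaks, and a set of 5724 peaks that passed an irreproducible discovery rate (IDR) threshold, per the deposited derivation records. The coordinates are on build dm6. The aligner, the peak caller, the number of reads and the IDR threshold were not given in the sources used here, so depth is unknown. The deposited signal value of each peak is the authors' own measure of peak strength, and it was used only to rank peaks within 1 list. The deposited −log10 q-value was at its ceiling of 4.08 in every IDR peak and was not used for ranking. The position of highest enrichment, here called the summit, was taken from the same lists. The IDR set consisted of the 5724 pooled peaks of highest signal. Some intervals carry more than 1 summit, with 36 repeated intervals in the IDR set, and each summit was counted as a peak.

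Genes came from the Ensembl 115 annotation of assembly BDGP6.54, which has the coordinates of dm6, and sequence from the release 6 genome. Transposable elements were left out. The 6 arms 2L, 2R, 3L, 3R, 4 and X held 18164 genes with 23998 distinct transcription start sites (TSSs), of which 19607 belonged to 13945 protein-coding genes. A peak was called promoter-proximal, and a gene bound, when a summit lay within 500 bp of a TSS. Each base was placed in the first class that applied among promoter, 5' UTR, 3' UTR, coding sequence, other exon, intron and intergenic. The class of other exons, mostly from non-coding transcripts, was added to the planned classes after the files were seen.

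Shares of summits in promoters, classes and arms were compared with the share of bases, or of protein-coding TSSs for arms, by exact binomial tests. Bound shares of 22 gene lists, of 6 non-coding gene classes and of divergent promoters were compared by Fisher's exact test. A total of 31 consensus motifs and all 2080 6-mers, with reverse complements joined, were searched within 100 bp of each summit. They were compared with a window of equal width 500 bp away on a side drawn at random, by the exact McNemar test. Motifs within 100 bp of bound and unbound protein-coding TSSs were compared by Fisher's exact test. Signal ranks of promoter and other peaks were compared with 100000 permutations. All tests were against both directions, and Benjamini-Hochberg adjustment was applied over the members of each family, with a threshold of 0.05. Intervals are exact at 95%. For a share of 0, the upper limit given is 3 counts divided by the number of genes, not an exact bound. Intervals and these limits cover counting error only. The mean and SD over replicates used the 5724 peaks of highest signal in each replicate's own list. An IDR peak counted as supported by a replicate when the windows of 100 bp on each side of the summits overlapped. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

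Gene lists, motifs, tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule took the tagged gene, the 15 promoter peaks of highest signal supported in all 3 replicates, the 5 such peaks away from promoters, up to 3 bound members of highest signal per list or non-coding class, and the 5 most enriched and 5 most depleted 6-mers by odds ratio with at least 50 discordant peaks. Some genes that this rule takes are not reported here. Alternatives covered other TSS distances, stricter peak sets, each replicate left out, other windows and control positions, another order of classes and 1 TSS per gene. To leave a replicate out, only IDR peaks supported by each of the other replicates were kept, 4088, 4197 and 4081 without replicates 1, 2 and 3. These sets are stricter and still come from the pooled list, so a change in them cannot be assigned to the replicate left out. For the overlap of replicates, the remaining pair was used. Keeping 1 summit per 1000 bp, and control windows matched on GC content without coding sequence, were added after seeing the data.

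The tests were checked on simulated data. The promoter test called 0 of 20 random sets of 5724 summits and 20 of 20 sets with planted promoter summits. The gene list test, run on 13945 genes, called 0 of 440 unchanged lists and 20 of 20 raised ones. The raised list was always that of the 73 mitochondrial ribosomal protein genes, so detection in smaller lists was not checked. The motif test called 0 of 93 motifs at random summits and 3 of 3 planted ones, and the 6-mer test called 0 of 6240 and 3 of 3, on 5724 summits each. Simulated summits were placed evenly over the arms, and simulated genes were bound independently. Real summit windows differ from their controls in GC content (37.0% against 42.8%), so these checks do not cover composition or neighbouring genes that share peaks.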

Results

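Binding of the CG13296 protein was mapped in whole embryos by ChIP-seq through a GFP tag, in 3 biological replicates of 1 group. CG13296, identifier FBgn0035687, is named Prdm13 in the annotation and belongs to the PR/SET domain family of zinc-finger proteins. The data ask where the tagged protein sits in the embryonic genome, beside which genes, and on which sequences. With a single group there is no treatment or genotype to contrast, so each comparison sets bound sites against the genome, against unbound genes or against neighbouring sequence. Read numbers were not given, so the depth of each library is unknown. Sample descriptions call the libraries input, against the other labels, and values are given for them as the immunoprecipitated samples.

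The strongest sites recurred in every replicate. The peak of highest signal lay in an intron of CG11050 (2L, 6612378 to 6612982) and ranked 2, 3 and 1 in replicates 1, 2 and 3. The next, 25 bp upstream of the TSS of Ugalt, a UDP-galactose transporter gene (X, 2703660 to 2704111), ranked 1, 1 and 4. Among the 5724 peaks of highest signal in each replicate, 74.5% ± 0.48 (SD, 3 pairs of replicates) overlapped a peak of another replicate, against 1.70% after random placement on the same arms. Of the 5724 IDR peaks, 84.0% ± 2.53 (SD, n = 3) were supported by a replicate's own top list, 3630 (63.4%) by all 3 and 33 by none. Ranks of the IDR peaks correlated across peaks with Spearman's rho of 0.714 for replicates 1 and 2, 0.666 for 1 and 3, and 0.722 for 2 and 3, where peaks are not independent replicates. The IDR set was chosen by the authors from these same replicates, so this support is not independent evidence.

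Peaks gathered at promoters. Summits lay within 500 bp of a TSS for 2996 of the 5724 IDR peaks, 52.3% (95% interval 51.0 to 53.6), where promoters cover 13.6% of bases, a 3.86-fold excess. The top lists of the replicates gave 53.1% ± 0.84 (SD, n = 3). Promoter summits sat at a median of -87.5 bp from the nearest TSS, where negative values are upstream, with quartiles at -185 and 13 bp, and 72.0% were upstream. Coding sequence was nearly empty, with 13 summits, 0.227% (0.121 to 0.388) against 13.1% of bases. The 3' UTRs held 1.31% of summits against 5.06% of bases, and intergenic sequence held 9.68% against 27.2%. Introns held 2004 summits, 35.0% (33.8 to 36.3) against 39.5% of bases, a 0.887-fold share. Coding sequence held 0.0173 times its share of bases for all IDR peaks, and 0.00934, 0.0109 and 0.0150 times without replicates 1, 2 and 3. Among peaks supported in all 3 replicates it held 0.0105 times that share. In the replicates introns held 34.4% ± 0.79 and coding sequence 0.233% ± 0.0993 (SD, n = 3). The 5' UTRs (0.852-fold) and other exons (0.938-fold) outside promoters did not differ from their share of bases, and the other 5 of 7 classes passed the exact binomial test. Introns reversed to a 1.13-fold excess when bases near a TSS were first given to the transcript class they lie in.

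**Figure D1:**
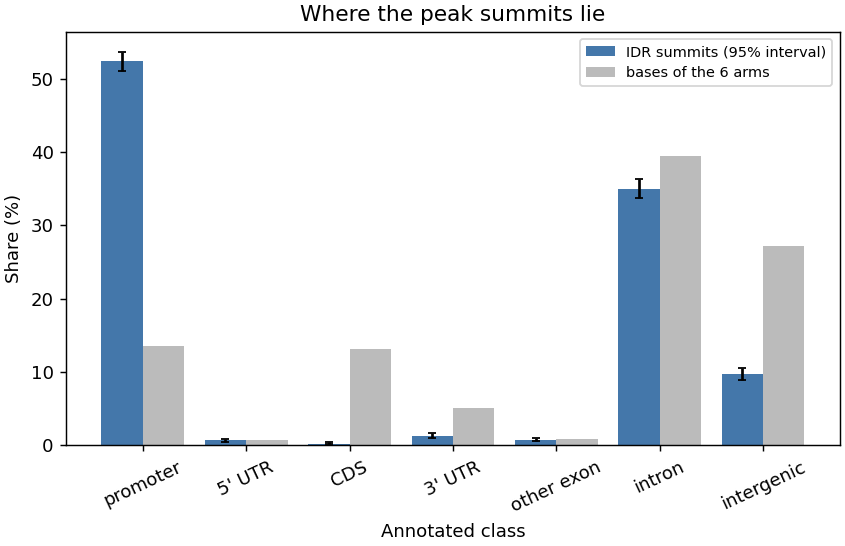
Share in percent of the 5724 IDR summits (blue, with exact 95% intervals) and of the bases of the 6 arms (grey) in each annotated class on the horizontal axis. Promoters hold 52.3% of summits and 13.6% of bases, and coding sequence 0.227% and 13.1%.

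Among promoter peaks, the highest signals after that of Ugalt were spread over genes of several functions. The next were CG14100 (rank 5, 3L, 19590408 to 19590832) and Gapdh2, a glycolytic enzyme gene (rank 6, X, 15867723 to 15868225, summit at -166 bp). The mitochondrial ribosomal protein genes mRpL41 (rank 8, 2R, 15217534 to 15218014) and mRpS10 (rank 15, 3R, 15229332 to 15229744) had summits at -132 and -125 bp. CG13390, CG18549, CG1635, Pal1, CG18428 and ph-p, a Polycomb group gene, held ranks 10, 11, 12, 14, 16 and 17. PNPase, which encodes polynucleotide phosphorylase, CG11309, CenG1A and Fkbp14 followed at ranks 18, 19, 20 and 23. All 15 of these peaks were within rank 49 of each replicate's list, and 13 of the 15 summits lay upstream of the TSS.

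Away from promoters, the peak of rank 3 lay in an intron of ush (2L, 480807 to 481360), which encodes a zinc-finger cofactor of GATA factors, and its nearest TSS was that of cbt, with the summit at -1368 bp. The peak of rank 4 (X, 12750829 to 12751669) lay in an exon of the non-coding gene lncRNA:Vinr. Rank 7 lay in an intron of Trl, the gene of the GAGA factor (3L, 14759292 to 14759778), with its summit 1527 bp downstream of the nearest TSS, also of Trl. Rank 9 lay in an intron of CG32772 (X, 4910054 to 4910621). Promoter peaks ranked higher than other peaks in signal, with a median percentile of 52.6 for 2996 peaks against 47.0 for 2728, a difference of 5.62 (permutation p = 2e-05). The difference was 4.15, 11.1 and 6.77 with the ranks of replicates 1, 2 and 3. Among all IDR summits, 687 were farther than 5 kb from any TSS.

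Ribosomal protein genes were the gene group bound most often of the 22 tested. Of 87 cytoplasmic ribosomal protein genes, 77 (88.5%) had a promoter peak, against 22.9% of other protein-coding genes (odds ratio 26.0, 95% interval 13.4 to 56.4, Fisher's exact test, adjusted p = 5.81e-37). The replicates gave 85.1% ± 2.30 (SD, n = 3). RpS27 (rank 91, 11 bp downstream of the TSS) and RpL13 (rank 181, 7 bp downstream) were among the members of highest signal. The odds ratio of the list was 16.1, 16.5 and 18.5 without replicates 1, 2 and 3, and 16.0 among peaks supported in all 3. Translation factor genes also passed, with 22 of 53 bound (41.5%, odds ratio 2.35, adjusted exact p = 0.0132), though not in the top list of replicate 2 alone (37.7%, adjusted exact p = 0.0652). Their highest signals were at eIF4EHP (rank 16), whose peak is shared with CG18428, eIF6 (rank 57) and eEF1gamma (rank 132). Of 73 mitochondrial ribosomal protein genes, 30 were bound (41.1%, odds ratio 2.31, adjusted exact p = 0.00391), led by mRpL41, mRpS10 and mRpS23, the last sharing its peak with CenG1A. In the replicates these lists reached 39.6% ± 1.89 and 39.7% ± 3.62 (SD, n = 3). The mitochondrial list's call was lost among the 2862 peaks of highest signal (odds ratio 1.53, adjusted exact p = 0.276), among peaks supported in all 3 replicates (1.86, adjusted exact p = 0.0767) and without replicate 3 (1.66, adjusted exact p = 0.156).

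Other housekeeping groups were not bound beyond other genes at the threshold. Respiratory chain genes were bound in 24 of 78 cases (30.8%, adjusted exact p = 0.234), with ND-ASHI, ND-42 and ND-51 highest. Proteasome genes were bound in 9 of 48 (18.8%, adjusted exact p = 0.742), among them Rpn11, Rpn12 and Rpn3. Cell cycle genes reached 9 of 30 (adjusted exact p = 0.569), with Dp, dup and Mcm2 highest. Of all 13945 protein-coding genes, 3244 (23.3%) were bound, 3251 ± 49.96 in the replicates (SD, n = 3).

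Some gene families had no bound member in the IDR set. None of 179 chemoreceptor genes had a promoter peak, 0 of 179, which by the limit of 3 counts allows a share of up to 1.68% (adjusted exact p = 2.87e-20), nor did any of 110 cuticle protein genes, which by the same limit allows up to 2.73% (adjusted exact p = 1.93e-12). Yolk and chorion genes (0 of 17, adjusted exact p = 0.0682) and Jonah protease genes (0 of 16, adjusted exact p = 0.101) did not pass at 500 bp. In the replicates' own top lists, 0.372% ± 0.645 of chemoreceptor and 0.606% ± 0.525 of cuticle protein genes were bound (SD, n = 3). Many of these genes lie in clusters, so their members are not independent and the p-values are too small.

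No list of developmental genes passed the threshold. These lists are small and their intervals wide. Odds ratios were 0.471 (95% interval 0.0104 to 3.67) for Hox genes and 2.94 (0.985 to 8.58) for ecdysone response genes. A list that did not pass may still differ from other genes. Neural genes were bound in 4 of 22 cases (18.2%, adjusted exact p = 0.801), although the promoter of elav, a neuronal RNA-binding protein gene, carried the peak of rank 43 (X, 523270 to 523715). Syx1A and fne were the next members. Segmentation genes were bound in 2 of 25 (hb and hry, adjusted exact p = 0.173) and Hox genes in 1 of 8 (Dfd, adjusted exact p = 0.778), whose peak was outside the relaxed list of replicate 1. Glial genes (3 of 10, moody, pnt and Nrt), muscle and mesoderm genes (6 of 21, with sls, tin and Act87E highest), gut and endoderm genes (4 of 11, with fkh, GATAe and kay) and epidermis and trachea genes (5 of 16, with trh, shg and bnl) had adjusted exact p-values of 0.778, 0.742, 0.462 and 0.742. Notch pathway genes were bound in 5 of 19 (adjusted exact p = 0.801), among them E(spl)m3-HLH, neur and mib1. The remaining 4 lists had larger shares that did not pass the adjustment. Ecdysone response genes were bound in 8 of 17 cases (47.1%, adjusted exact p = 0.104), led by E23, Eip75B and Hr78. With 1 TSS per gene their share was 5 of 17 (29.4%, adjusted exact p = 0.589). Heat shock genes reached 7 of 17 (41.2%, adjusted exact p = 0.173), led by Hsp83, Hsp27 and Hsp22. Polycomb and trithorax group genes reached 10 of 25 (40.0%, adjusted exact p = 0.141), led by ph-p, brm and E(z). In the replicates' own top lists the share of this list was 48.0% ± 8 (SD, n = 3), and it passed in those of replicate 2 (12 of 25, adjusted exact p = 0.0336) and replicate 3 (14 of 25, adjusted exact p = 0.00226). Genes of Wnt, Hedgehog, BMP and EGFR signalling reached 11 of 28 (39.3%, adjusted exact p = 0.152), led by spi, nkd and aos. Among peaks supported in all 3 replicates the heat shock and the Polycomb and trithorax lists passed, both with adjusted exact p = 0.0438.

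**Figure D2:**
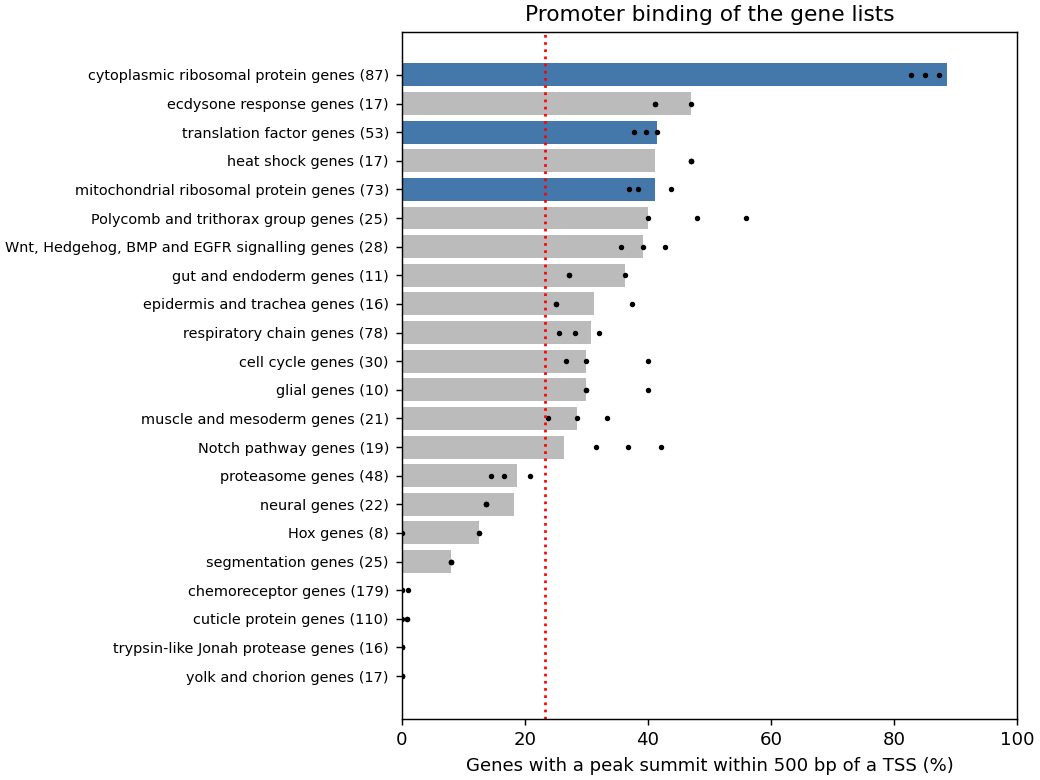
Percent of the genes of each list (number of genes in brackets) with an IDR summit within 500 bp of a TSS, as bars, blue where Fisher's exact test passed after adjustment, with the top list of each replicate as a point and the share of all protein-coding genes as a dotted line at 23.3%. Cytoplasmic ribosomal protein genes reach 88.5%, and the bars of chemoreceptor and cuticle protein genes are at 0.

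Of 6 classes of non-coding genes, all but snRNA genes were bound less often at the threshold than the 23.3% of protein-coding genes. Any TSS of a gene counted, and the 13945 protein-coding genes had 19607, which gave some of them more chances. With 1 TSS per gene 2881 of them were bound, and the non-coding classes were not compared in that way. Peaks lay at 41 of 290 tRNA genes (14.1%, odds ratio 0.543, adjusted exact p = 0.000211), 25 of 269 snoRNA genes (9.29%, odds ratio 0.338), 265 of 3261 other non-coding RNA genes (8.13%, odds ratio 0.292) and 8 of 268 pseudogenes (2.99%, odds ratio 0.102). The tRNA odds ratio was 0.481, 0.315 and 0.348 without replicates 1, 2 and 3, and 0.287 among peaks supported in all 3. The replicates' own top lists held 9.66%, 17.9% and 15.5% of tRNA genes. No rRNA gene was bound (0 of 99, which by the limit of 3 counts allows up to 3.03%). The 3 of 32 snRNA genes bound were snRNA:7SKa, snRNA:U2:34ABb and snRNA:U6:96Ac (9.38%, adjusted exact p = 0.0902), and this class passed without replicate 1 (odds ratio 0.151) or 2 (0.145) but not without replicate 3 (0.313, adjusted exact p = 0.105). The top lists of replicates 1, 2 and 3 held 18.8%, 9.38% and 6.25% of snRNA genes, and the class passed in that of replicate 3 alone, with an odds ratio of 0.768 in that of replicate 1. The tRNA gene with the highest signal was tRNA:Tyr-GTA-1-8 (rank 118), followed by tRNA:Phe-GAA-1-2 and tRNA:Leu-TAA-2-1. The snoRNA genes snoRNA:Or-aca5 and snoRNA:Psi28S-2949 share the peak of rank 135, snoRNA:U49:66Da follows at rank 255, and lncRNA:CR44463, lncRNA:CR31840 and lncRNA:CR46036 lead the other non-coding genes at ranks 8, 28 and 36. The peak at lncRNA:CR44463 is that of mRpL41. How the authors treated reads that map to several copies, as in rRNA and tRNA genes, was not given in the sources used here. Genes that lie close together can share a peak and are not independent, so the p-values and the limit for rRNA genes are too small. The snoRNA share depended on the distance. With 200 bp in place of 500 bp it was 9 of 269 (3.35%, odds ratio 0.169), and with 1000 bp 71 of 269 (26.4%), where the call was lost (odds ratio 0.966, adjusted exact p = 0.836).

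Promoters in divergent pairs were bound more often than others. Of 4457 protein-coding TSSs with the TSS of another gene on the opposite strand, pointing away, within 500 bp, 1749 (39.2%) were bound, against 2541 of 15150 others (16.8%, odds ratio 3.20, 95% interval 2.97 to 3.45, Fisher's exact test p = 7.76e-204). The replicates gave 38.9% ± 2.27 against 17.1% ± 0.43 (SD, n = 3). A summit between the 2 TSSs of a pair counts for both, and 2 independent promoters with the share of the others would have at least 1 bound in 30.7% of cases. TSSs of 1 pair or 1 gene are not independent, so the interval is too narrow and the p-value too small.

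In the IDR set, none of the 6 chromosome arms differed at the threshold from its share of protein-coding TSSs. The X carried 970 peaks, 16.9% (16.0 to 17.9) against 16.9% of TSSs, a ratio of 1.00. Arm 3L held 1.05 times its TSS share (unadjusted exact binomial p = 0.0481, adjusted p = 0.209), and arm 4 held 33 peaks, 0.796 times its share (adjusted p = 0.423). Arm 4 fell below its share when replicate 1 was left out (0.507, adjusted exact p = 0.0321), when replicate 3 was left out (0.508, adjusted exact p = 0.0320), and against its share of bases (0.573, adjusted exact p = 0.00333). It did not pass without replicate 2 (0.790, adjusted exact p = 0.549) or among peaks supported in all 3 replicates (0.533, adjusted exact p = 0.0832). In the top list of replicate 2 alone, arms 3L (1.07) and 4 (0.579) both passed (adjusted exact p = 0.0232), and in the pooled relaxed list of 30000 peaks 2R (0.873, adjusted exact p = 3.84e-29) and 3L (1.13, adjusted exact p = 1.29e-26) passed.

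Several promoter sequences were more frequent at summits than beside them, though not all. The DNA replication element TATCGATA, the site of DREF, lay within 100 bp of 3.13% of summits and in 0.594% of control windows (odds ratio 5.39, exact McNemar test, adjusted p = 9.51e-24). In the replicates it lay at 2.89% ± 0.116 of summits (SD, n = 3). The site of the promoter factor M1BP (Ohler motif 1) lay at 1.03% against 0.192% (odds ratio 5.36, adjusted exact p = 1.98e-08), and Ohler motif 7 at 6.52% against 3.25% (odds ratio 2.10, adjusted exact p = 2.04e-15). The forkhead site was found at 9.22% of summits against 5.22% (odds ratio 1.87), and the Mef2 site at 11.7% against 6.76% (odds ratio 1.83). Odds ratios were 2.67 for Ohler motif 6, 2.00 for the CTCF core, 1.80 for the TATA box, 1.41 for the homeodomain site, 1.40 for the BEAF-32 core and 1.35 for the GATA site. The Pleiohomeotic site (0.762) and the CA repeat (0.732) were less frequent at summits, and 13 of 31 motifs passed in all. The core promoter elements Initiator (18.5% against 17.7%, odds ratio 1.06) and DPE, found at 1 summit, did not pass, nor did the Zelda (0.844), GAGA (0.974) and Grainyhead (0.957) sites. With 1 discordant peak the DPE test could not pass. Many promoter summits lay upstream of the TSS, which can leave both elements outside the window. Among summits farther than 500 bp from a TSS, the elements TATCGATA (0.615), M1BP (0.333) and Ohler 7 (0.833) showed no enrichment, while forkhead (2.28), Mef2 (1.66) and the CTCF core (3.27) passed. Control windows 500 bp from these summits can fall on promoters, which can lower the odds ratios of promoter elements. With control windows matched on GC content and free of coding sequence, the TATA box (1.15), GATA (0.972), homeodomain (0.970), Ohler 6 (1.39) and CA repeat (0.934) calls were lost, while TATCGATA (2.92), M1BP (2.00), Ohler 7 (1.98), forkhead (1.53), Mef2 (1.16, 11.6% against 10.2%) and the CTCF core (2.44) passed, and sites that had not passed beside the first control did so with these windows, namely the E-box CAGCTG (1.57), Ets (2.25), E2F (1.34) and GAGA (1.33). The CTCF core was lost among the 2862 peaks of highest signal (1.33) and without replicate 1, 2 or 3 (1.24, 1.36 and 1.73). Ohler 6 was lost without replicate 1 (2.33) or 2 (2.00), and among the 2862 peaks of highest signal, where its odds ratio was 3.25 (adjusted exact p = 0.127).

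At the level of 6-mers, summits had more A and T than the sequence beside them. Windows at summits had a mean GC content of 37.0% and control windows 42.8%. AAATAT (odds ratio 2.40, in 49.9% of summit windows against 29.2%), AGTGTA (2.34), CGATAG (2.32), AATATT (2.28) and ACACTG (2.26) were the most enriched. CCAGGA (0.189, in 1.55% against 7.77%), GAGGAC (0.226), CAGGAC (0.252), CAGGAG (0.266) and CTCCTC (0.270) were the most depleted. Of 2080 6-mers, 1387 passed the exact McNemar test after adjustment, 461 enriched and 926 depleted. With the matched control windows 383 passed, and all 10 named 6-mers kept their direction and passed, AAATAT at 1.49 and CCAGGA at 0.480.

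Bound promoters also differed from unbound ones in sequence. Ohler motif 7 lay within 100 bp of 15.3% of 4290 bound protein-coding TSSs and of 7.998% of 15317 unbound ones (odds ratio 2.07, Fisher's exact test, adjusted p = 1.23e-40). TATCGATA lay at 9.28% against 5.63% (odds ratio 1.71, 95% interval 1.51 to 1.94), and the E-box CAGCTG at 18.3% against 12.2% (odds ratio 1.61). GAGA (1.57), Ohler 6 (1.54), the E-box CACGTG (1.54), forkhead (1.45), M1BP (1.43), the CA repeat (1.34), the BEAF-32 core (1.30) and E2F (1.204) sites were more frequent at bound promoters. The TATA box, at 3.73% against 7.65% (odds ratio 0.468, adjusted exact p = 1.40e-20), the initiator (0.758) and the TCF site (0.821) were less frequent, and 14 of 31 motifs passed in all. TSSs of 1 gene or 1 divergent pair share sequence, and with 1 TSS per gene the CA repeat, TCF and E2F calls were lost (adjusted exact p = 0.113, 0.0523 and 0.305). Among the 2862 peaks of highest signal these calls and that of M1BP (odds ratio 1.27) were lost (adjusted exact p = 0.187, 0.218, 0.06998 and 0.0907).

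The CG13296 gene itself, 1556 bp on arm 3L (6163127 to 6164682, plus strand), held no peak in any list. Within 10000 bp on either side, the relaxed lists of replicates 1, 2 and 3 held 8, 7 and 7 peaks, against 5.06, 4.92 and 5.00 from the density of the arm. The only IDR peak there (rank 833, 6157747 to 6157948) lay 447 bp from the TSS of CG13297, and it ranked 1195, 884 and 649 in the replicates. The locus was chosen in advance because the tagged line was taken to carry copies of this gene. Extra copies could raise the signal around it, which was not tested, so these peaks cannot be assigned to binding.

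The promoter share of summits declined with peak rank in each list. In bins of 3000 peaks of the pooled list, the promoter share was 55.0% at ranks 1 to 3000 and 49.6% at ranks 3001 to 6000.

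**Figure D3:**
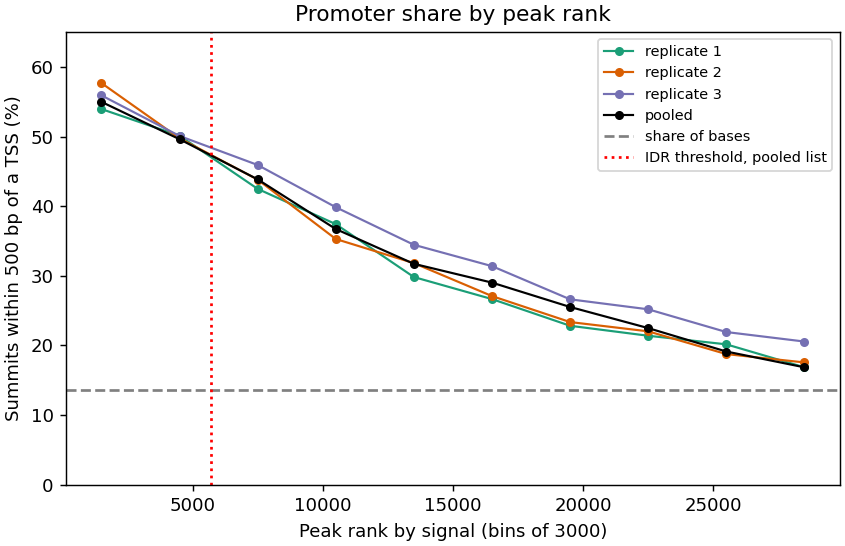
Percent of summits within 500 bp of a TSS in bins of 3000 peaks ranked by signal, for the 3 replicate lists and the pooled list, with the share of bases (13.6%) as a dashed line and the IDR threshold of the pooled list as a dotted line. The pooled share goes from 55.0% in the first bin to 16.9% in the last.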

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

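The look at peaks below the IDR threshold was chosen after the report's results were seen. The comparisons of the report rest on IDR peaks, and the relaxed pooled list carried promoter signal beyond them. At ranks 6001 to 9000, 43.9% of 3000 summits (95% interval 42.1 to 45.7) lay within 500 bp of a TSS, where 13.6% of bases do. At ranks 27001 to 30000 the share was 16.9% (15.5 to 18.3, exact binomial p = 2.56e-07).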

How the results depend on the processing

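Of the alternatives below, keeping 1 summit per 1000 bp and the GC-matched control windows without coding sequence were chosen after the data were seen. The promoter share stayed above the share of bases under all 8 alternatives (37.6% at 200 bp to 62.8% at 1000 bp), and the divergent odds ratio lay between 2.63 and 3.62. With the promoter class placed after the transcript classes, the fold over bases turned to 4.18 for 5' UTRs, 1.34 for other exons and 1.13 for introns, by the construction of that order. Between 0 and 1 arm passed when each replicate was left out and 1 against the share of bases, arm 4 each time among these alternatives. The overlap of replicates was 80.1% for the top 1000 peaks and 74.0% to 74.99% with each replicate left out. At 1000 bp, 8 gene lists passed in place of 5, adding yolk and chorion, Jonah protease and signalling genes (adjusted exact p = 0.0287 each). Summits away from TSSs gave 7 motifs in place of 13, with odds ratios of 0.615 for the DNA replication element, 0.333 for M1BP and 0.833 for Ohler 7, in fewer peaks. The control windows of these summits can fall on promoters. The control 1000 bp away turned GAGA to 1.36 and the CA repeat to 1.03. The GC-matched control turned GAGA to 1.33, Ets to 2.25, E2F to 1.34, GATA to 0.972 and the homeodomain site to 0.970, where GAGA, Ets and E2F passed and GATA and the homeodomain site did not, raised the E-box CAGCTG from 1.02 to 1.57, and left 383 6-mers in place of 1387. These windows changed GC content and coding sequence together, so the cause was not tested. Motifs below the threshold passed with a replicate left out for Zelda (0.771 without replicate 2, 0.725 without 3), Twist (1.32 and 1.25) and Sox (0.680 without 2). The Su(Hw) core, at 1.57 and not called in all IDR peaks, passed among peaks supported in all 3 replicates (2.50) and with 1 summit per 1000 bp (2.33). Twist also passed with 1 summit per 1000 bp (1.22), and CRE (0.448) and Zelda (0.727) among peaks supported in all 3 replicates. Zelda (0.634), GAGA (0.701) and CACGTG (0.633) passed with windows of 50 bp on each side, GAGA (0.535) away from TSSs, and Twist (1.32), Sox (0.667), CAGCTG (1.202) and CACGTG (0.744) with the control 1000 bp away. At bound promoters with a replicate left out, the calls of E2F (1.14 without 1, 1.12 without 2), the CA repeat (1.21 without 2) and TCF (0.857 without 2) were lost. No read numbers were given, so limits from depth cannot be set.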

Other observations

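The counts per gene body, the look at unbound ribosomal protein genes, and the tests of neighbouring genes, of the pyrimidine initiator and of matched control windows were chosen after the report's results were seen. Away from promoters, some genes held many IDR summits within their bodies. Counting only summits farther than 500 bp from any TSS, ush (2L, 476220 to 540560) held 13 in 64.3 kb. CHES-1-like, a forkhead factor gene (X, 7682338 to 7709385), held 11 in 27.0 kb, a density of 4.07 per 10 kb, and Mnt (X, 3671801 to 3701672) held 9 at 3.01 per 10 kb. CG1677 held 12, the genes rdx, sbb and shn 11 each, and Raf and Tlk 10 each. These genes were named from their counts, and no test was run.

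Cytoplasmic ribosomal protein genes without a promoter peak included RpL10Aa, RpL15, RpL21, RpS10a, RpS15Ab, RpS19b, RpS24, RpS26 and RpS5b. Several of them are second copies of a ribosomal protein gene by their names, such as RpS5b, RpS10a and RpS19b. RpS24 and RpS26 were bound in the top list of at least 1 replicate.

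The first pattern is the binding of ribosomal protein promoters. Peaks of neighbouring genes are argued against as the whole source: among genes with no TSS of another gene within 1000 bp, 12 of 18 cytoplasmic ribosomal protein genes were bound against 14.1% of 7201 others (odds ratio 12.1, 4.21 to 39.5, Fisher's exact test p = 5.42e-07). A signal that follows high transcription at any promoter stays open. Cytoplasmic genes were bound more often than mitochondrial ones (odds ratio 10.8, 4.65 to 27.5, Fisher's exact test p = 1.51e-10). That comparison reuses the counts of the pattern itself, 77 of 87 against 30 of 73, so it lends this explanation no separate support. No expression was measured here, and proteasome genes were bound in 18.8% of cases. The pyrimidine initiator YCTTTY within 5 bp of a TSS position was found in 53 of 87 cytoplasmic ribosomal protein genes (60.9%). Of the 34 genes without it, 28 (82.4%) were bound, against 22.5% of other genes without it (odds ratio 16.1, 6.53 to 47.6, Fisher's exact test p = 2.39e-13). Those other genes leave out mitochondrial ribosomal protein and translation factor genes. An initiator away from an annotated TSS or with another sequence would be missed, so this cannot exclude it as the whole source. The initiator stays open, as among the other genes 34.7% of 236 with it were bound (odds ratio 1.84, 1.38 to 2.42, Fisher's exact test p = 2.03e-05), against 92.5% of the 53 ribosomal protein genes with it. No biological explanation from the design was tested, since there is 1 group.

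The second pattern is the sequence at summits. TATCGATA may be a sequence of promoters in general: bound promoters held it more often than unbound ones at an odds ratio of 1.71 (1.51 to 1.94), which lies between the bounds of 1.5 and 2 set in advance, so this cannot be told apart from a preference of the protein. The odds ratio was under 1.5 among the 2862 peaks of highest signal (1.44) and among peaks supported in all 3 replicates (1.48), on the side of promoters in general, with intervals that reach 1.68 and 1.71. It stayed between the bounds without replicate 1, 2 or 3 (1.52, 1.58 and 1.5015), with 1 summit per 1000 bp (1.75) and with 1 TSS per gene (1.78). TATCGATA sites were spread rather than centred on summits. Bins of 50 bp within 150 bp of an IDR summit held 7.34 to 9.08 sites per 1000 peaks. The outermost bins, 450 to 500 bp away, held 1.05 upstream and 1.22 downstream in coordinates. This spread was not tested and does not settle the question. The low GC content of summits and the coding sequence in control windows could account for part of the A and T rich 6-mers, as the odds ratio of AAATAT went from 2.40 to 1.49 (adjusted exact p = 8.60e-20) with matched windows, short of the bound of 1.5 set for excluding it. With those windows ACAGTG (2.00) and ACACTG (1.91) had the highest odds ratios. No biological explanation from the design was tested.

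The third is a negative result. A mixed population of males and females carries fewer copies of X than of the autosomes, which could lower the number of peaks called there. The ratio of the X share of peaks to its share of TSSs was 1.00 (95% interval 0.947 to 1.06, exact binomial adjusted p = 0.888), neither below nor above 1 beyond its interval, so no loss on X was seen and the hypothesis stays undecided.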
